A study of Mus musculus with 12 samples.

How the data were processed

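CD45+ leukocytes of 4 new-onset diabetic NOD mice, 14 to 18 weeks old, were profiled by CITE-seq in pancreas and blood. Per the labels' protocols, cells were blocked for Fc receptors and stained with 190 TotalSeq-A antibodies that carried barcodes, together with a CD45 antibody (clone 30-F11) for the sort, sorted for CD45, and loaded on 10x Genomics 3' version 3.1 chemistry with a target of 10000 cells per library. Per the labels, mice were pooled in pairs, and each of the 2 pools gave an mRNA, an antibody and a hashtag library from each of the 2 tissues, or 12 samples in 6 groups. The mRNA, antibody and hashtag libraries of a pool were sequenced together in unequal proportions, per the labels' protocols.

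The deposited values are raw UMI counts per feature and cell barcode, held in 4 matrices that each combine genes, antibodies and hashtags. Per the submitters' processing notes Cell Ranger, Seurat 4.1.0 and the build GRCm38 were used; the version of Cell Ranger, its gene annotation and the filters behind the 43706 cells that the series states were not given in the sources used here. The names of the matrices mark them as Cell Ranger's filtered output, and their values were whole numbers with unequal totals, so no normalization by the authors had been applied. Each matrix held 55385 genes, of which 55144 matched by ID to GENCODE M21 (GRCm38), 191 antibody features with 10 isotype controls among them, and 24 hashtag features. The features are thus 1 more than the 190 antibodies stated, and 181 were not isotype controls. Of the antibodies, 14 had at most 3 UMI in every matrix. Positions of named genes were taken from GENCODE M21 by gene ID.

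No label, column or feature name tied a matrix to a sample, and hashtags were named by number only. The tests between pancreas and blood that had been planned before the data were examined (a count test of genes per class, an exact permutation test of class shares and a test of protein levels) had been made conditional on such a tie and were not run. The matrices are called 1 to 4 in no meaningful order. Each is described by its own values, without a mean over matrices, a standard deviation or a p-value, because cells are not replicates. A sum of UMI has an exact Poisson interval and a share of cells an exact binomial (Clopper-Pearson) interval, both at 95%, and both cover counting error only. For a count of 0 the same exact interval gives an upper limit above 0. Free RNA in the droplets adds UMI to cells that do not express a gene, and free antibody does the same for proteins.

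Cells with at least 200 genes and at most 10% mitochondrial UMI were kept, which left 12061, 10144, 11719 and 11218 of 12205, 10230, 13770 and 12055 barcodes. A cell with at least 5 hashtag UMI was given to hashtag 1 or 2 when at least 80% of them came from it, and called a doublet when both hashtags were present and neither reached that share. These doublets amounted to 4.54%, 5.17%, 4.97% and 3.99% of cells. Scrublet, as implemented in scanpy with an expected rate of 9%, called 4.06%, 5.89%, 8.21% and 6.11%, and both kinds were removed, which left 11222, 9289, 10419 and 10298 cells.

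All 4 matrices were clustered together on RNA alone and without integration, with counts per 10000 on a log scale, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. T- and B-cell receptor genes were left out of the variable genes. The T cells and the mixed myeloid and plasma cells among 28 first clusters were clustered again, giving 17 T subclusters (named T0 to T16) and 13 others (M0 to M12), 47 clusters in all. Clusters were named "X-like" from 28 marker lists fixed before the data were examined, by the type with the highest mean fold of its markers among types with at least 3 markers that were seen in 10% of the cells at 2 times the level of other cells. A cluster stayed unnamed if its 10 leading genes held more markers of another type than of its own. This gave 21 classes, a cluster led by acinar genes, and unnamed cells, which made up 3.08%, 2.62%, 0.278% and 0.418% of the matrices. The cells near a naming limit were not moved by hand.

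Gene and list levels are UMI per 10000 UMI of a class, and antibody levels UMI per 10000 antibody UMI, for classes with at least 20 cells in a matrix. An antibody was called above background where its value exceeded the highest isotype control of the same class and matrix. For shares of cells with a UMI, each of the 41228 cells was also drawn down to 500 UMI. Of 130 antibody and gene pairs matched by name, the 55 whose RNA reached 0.5 UMI per 10000 in some class of every matrix and whose antibody exceeded the isotype control entered the correlations.

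The genes named were fixed by rule before the data were examined, namely the 4 members with the highest level in any class of each of 16 lists (cytotoxic, inhibitory receptors, naive and stem-like, tissue residency, helper and follicular, regulatory, interferon response, antigen presentation, chemokines, inflammatory, dissociation stress, proliferation, germinal centre B, pancreas parenchyma, platelet and erythroid). Of the antibodies, the rule took the 5 per class with the highest ratio to the mean of the other classes among those above the isotype control in every matrix with the class, and 7 antigens that vary between strains. Some of the genes and antibodies that the rule took were not used here. The rule also took the 5 pairs with the highest and the 5 with the lowest median correlation of RNA and protein. Genes and antibodies of single T and myeloid subclusters were chosen after their values were seen. The gene H2-Ea of the antigen presentation list was not found under that name.

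Alternatives planned before the data were examined were a minimum of 500 genes, a mitochondrial limit of 5%, doublets kept, resolutions of 0.5 and 2, receptor genes kept, 3 times the isotype control, a centred log-ratio of the antibodies, correlation over single cells, and thinned cells. Added after seeing the data were isotype controls without the one named IgG2a, values without the cell with the most UMI of an antibody, and shares over cells with 1 hashtag.

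The steps were tested on simulated data drawn from the real means. In B-like cells of matrix 1, with 19221 genes, the Poisson interval covered the true level of 96.2% of genes, all genes changed 2-fold or 4-fold were told apart (median ratios 1.99 and 4.00), and 0.363% of unchanged genes were. The coverage was 96.9% over 15679 genes in neutrophil-like cells of matrix 3 and 96.5% over 14071 genes in NK-like cells of matrix 4. These counts were drawn with counting error only, which is what the Poisson interval assumes, so its coverage followed from the draw. The coverage and the changes told apart check the calculation only. They cannot show how the interval performs where real cells of a class vary by more than counting. Clustering and naming put 100% of 400 simulated cells of each of 6 classes of matrix 1 under their own name, over 18939 genes. These cells were drawn from the mean of each class as named, without doublets, other matrices or variation within a class beyond depth and counting. The test could therefore not show clusters that mix lineages. Thinning kept 99.9% of 7657 genes of B-like cells of matrix 1 within 3 standard deviations of the level drawn. All of 50 antibodies simulated at 2 times the isotype control in B-like cells of matrix 1 were called above it and 0% of those at 0.5 times. With protein made proportional to RNA in matrix 1 the median correlation over 112 genes was 0.967, and -0.0204 when shuffled.

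Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, python-igraph 0.11.9 and matplotlib 3.10.9. Random seeds were at 0, except in the tests of the steps, which also used other seeds.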

Results

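The data came from a single-cell survey of the leukocytes of non-obese diabetic (NOD) mice, an inbred strain that develops autoimmune diabetes spontaneously. According to the labels, 4 mice aged 14 to 18 weeks with newly arisen diabetes were used, and CD45+ leukocytes were sorted from their pancreas and from their blood. Each cell was read out in 3 ways by CITE-seq, which sequences a cell's mRNA together with the DNA barcodes of antibodies bound to its surface (antibody-derived tags) and with a hashtag antibody that marks the animal of origin. The labels listed 12 samples in 6 groups, made of 2 tissues and 3 kinds of library, with 2 pools of 2 mice in each group. The counts were held in 4 matrices whose names shared no code with any label, so none of them could be tied by label to a tissue or to a pool. Values that set matrices 1 and 2 apart from matrices 3 and 4 are given below, but no matrix was assigned to a tissue from them. The question named in the series title, which leukocytes are found in pancreas and which in blood at diabetes onset, was therefore addressed only as a description of each matrix, and no comparison between tissues was made. Values are given in the order of matrices 1 to 4 wherever 4 values follow each other, and intervals are exact 95% intervals that cover counting error only. There were no replicates of known group.

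The matrices held 12205, 10230, 13770 and 12055 cell barcodes, or 48260 in total, with 53446294, 47162611, 28339262 and 43245093 mRNA UMI (unique molecular identifiers, one per captured molecule). The antibody counts came to 2629487, 3315344, 1671591 and 2981537 UMI. After filters on genes and mitochondrial RNA 45142 cells passed, and 41228 remained once doublets were taken out, beside the 43706 that the series states after its own filtering. The median cell had 3400, 3503, 1513 and 2743 mRNA UMI and 186, 273, 96 and 194 antibody UMI, so that matrix 3 was the shallowest in both readouts. Of the kept cells of each matrix, 4.65%, 3.14%, 50.4% and 23.1% carried fewer than 5 hashtag UMI and were given to neither of the 2 mice of their pool.

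B-like cells, named by Cd79a, Ms4a1 and 6 other B-cell genes, were the most frequent class in matrices 1 and 2 and second in matrix 4, with 30.2%, 31.1%, 26.7% and 28.9% of cells. Their clusters differed by matrix, as cluster 1 had 1943, 1976, 66 and 245 cells, cluster 13 had 1051, 424, 4 and 1, and cluster 15 had 258, 316, 2657 and 2556. Cluster 13 also met 7 markers of the acinar list. In matrix 3 B-like cells were level with neutrophil-like cells, at 2786 and 2782 cells, and with a mitochondrial limit of 5% the shares there were 22.1% and 32.5%. Neutrophil-like cells ranged far more widely, from 4.61% (4.23 to 5.01%) in matrix 1 and 4.51% (4.098 to 4.95%) in matrix 2 to 26.7% (25.9 to 27.6%) in matrix 3 and 31.7% (30.8 to 32.6%) in matrix 4. CD4 T-like cells made up 22.7% (22.0 to 23.5%), 20.4% (19.6 to 21.2%), 0.950% (0.773 to 1.16%) and 7.31% (6.82 to 7.83%), and CD8 T-like cells 15.03%, 15.6%, 6.95% and 5.61%. The CD4 T-like share of matrix 3 leaves out cells that were CD4 by antibody, since these made up 64.7% of scored cells in T16, which supplied 904 of its 909 T-like cells, and 55.5% in the CD8 T-like subcluster T11. NK-like cells amounted to 5.94%, 8.88%, 2.97% and 3.24%, and Treg-like cells, the Foxp3-expressing T cells that restrain autoimmune responses, to 3.99%, 2.56%, 1.57% and 1.57%. A further T-like class, in which neither the CD4 nor the CD8 gene list led, held 4.54%, 3.61%, 8.72% and 1.30% of cells. It was made up of T1 in matrices 1 and 2 and for 102 of 134 cells in matrix 4, where 95.2%, 94.6% and 98.0% of scored cells were CD8 by antibody, and of T16 for 904 of 909 cells in matrix 3, so the CD8 T-like shares leave out CD8 cells. The neutrophil-like share of matrix 3 fell to 11.1% when only cells given to 1 hashtag were counted, and its CD8 T-like share was 3.12% with a mitochondrial limit of 5%. At other clustering resolutions the T-like class of matrices 1 and 2 dropped to 0.0356% and 0.0215% as its main subcluster passed to the CD8 T-like class.

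**Figure D1:**
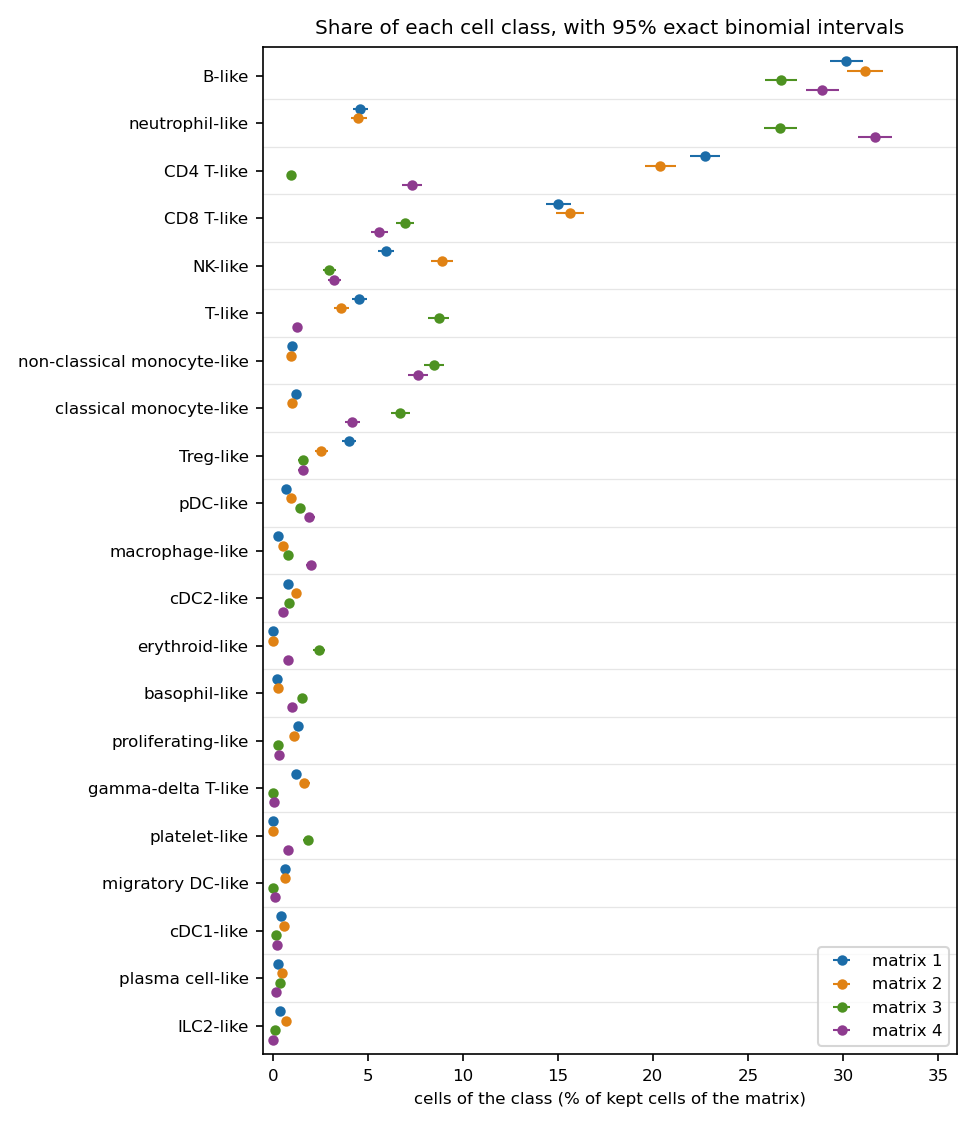
Share of kept cells (percent) in each RNA-defined class, with 1 point per matrix and exact 95% binomial intervals as bars. B-like shares lay between 26.7% and 31.1% in the 4 matrices, whereas neutrophil-like shares ran from 4.51% to 31.7%.

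Monocytes, dendritic cells and rarer leukocytes were present in every matrix at unequal frequencies. Non-classical monocyte-like cells, marked by Ace and Treml4, made up 0.998%, 0.958%, 8.48% and 7.64% of cells, and classical monocyte-like cells, with Ly6c2 and Vcan, 1.25%, 0.990%, 6.72% and 4.17%. Plasmacytoid dendritic (pDC)-like cells held 0.722%, 0.947%, 1.45% and 1.93%, and basophil-like cells 0.2495%, 0.291%, 1.55% and 1.01%, or 28, 27, 161 and 104 cells. Gamma-delta T-like cells amounted to 1.25%, 1.67%, 0.0192% and 0.0486%, and migratory DC-like cells, with Fscn1 among the leading genes of both their clusters, to 0.633%, 0.646%, 0.0384% and 0.136%. Type 1 and type 2 conventional dendritic cell-like (cDC1 and cDC2) shares were 0.410%, 0.614%, 0.163% and 0.233% and 0.829%, 1.23%, 0.854% and 0.563%. Cluster M6, with 34 and 58 of the cDC2-like cells of matrices 1 and 2, met 6 macrophage markers and 5 cDC2 markers. The cDC2-like values of these matrices thus rest partly on cells that also carried macrophage genes. Macrophage-like cells accounted for 0.294%, 0.538%, 0.787% and 2.00%, group 2 innate lymphoid cell (ILC2)-like cells for 0.392%, 0.678%, 0.125% and 0.0291%, and plasma cell-like cells for 0.285%, 0.506%, 0.394% and 0.184%. Erythroid-like cells held 0.0267%, 0.0215%, 2.42% and 0.825%. No platelet-like cell was found in matrices 1 and 2, which allows shares of up to 0.0329% and 0.0397%, against 1.84% and 0.825% in matrices 3 and 4.

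The 2 hashtags of each matrix, taken as the 2 mice of its pool, differed in several of these shares. Neutrophil-like cells made up 1.81% of hashtag 1 cells and 7.48% of hashtag 2 cells in matrix 1, 6.62% and 2.49% in matrix 2, 13.1% and 9.22% in matrix 3, and 29.3% and 18.2% in matrix 4. CD4 T-like cells amounted to 25.6% and 18.6%, 14.9% and 25.0%, 1.12% and 2.00%, and 10.2% and 8.28% for hashtags 1 and 2 of the same matrices. Gamma-delta T-like cells stood at 0.697% and 2.20% in matrix 1 and at 2.33% and 1.02% in matrix 2. Cells with fewer than 5 hashtag UMI were neutrophil-like in 19.0%, 12.7%, 42.1% and 61.5% of cases, so the hashtag shares leave out a part of the neutrophils that differs between matrices. Basophil-like cells made up 2.87%, 5.82%, 2.80% and 3.62% of these cells, but 0.119% and 0.126%, 0.105% and 0.116%, 0.456% and 0.109%, and 0.123% and 0.3004% of hashtags 1 and 2 in turn. Erythroid-like cells of matrix 3 fell from 3.94% of them to 0.912% and 0.835%, and plasma cell-like cells of matrix 1 from 3.26% to 0.0593% and 0.278%. Which mouse carried which hashtag was not given in the sources used here.

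Within the T cells, subclusters differed in their leading genes. Subcluster T4 of the CD8 T-like cells, led by the integrin genes Itgae and Itga1 and by the chemokine receptor gene Cxcr6, had 482, 527, 0 and 0 cells. Cxcr6 stood at 17.3 (16.6 to 17.9) and 17.8 (17.1 to 18.4) UMI per 10000 in T4 of matrices 1 and 2, against 7.67 and 7.87 in T3 and 10.1 and 11.3 in the CD4 T-like T8, and its CD103 antibody, against the protein of Itgae, at 227 and 258 per 10000 antibody UMI. Subcluster T3, led by the granzyme gene Gzmk, had 918, 655, 5 and 60 cells, and T11, led by Gzma and Klrg1, had 44, 28, 440 and 146. Gzma reached 62.6, 83.0, 27.6 and 66.6 UMI per 10000 in T11. Subcluster T7, a CD8 T-like population, had 133, 134, 276 and 369 cells. As the subclusters were made from these genes, the RNA values describe the clusters and are not independent findings, whereas the antibody values are a separate readout. T4 had no cell in matrices 3 and 4 and T16 none in matrices 1 and 2, so whether they stand for a cell type or for those libraries was left open. The leading genes of T16 included Gm42418, Lars2 and mt-Rnr1, and its median cell had 1225 UMI in matrix 3, so low RNA quality was not excluded for it.

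The surface proteins followed the RNA-defined classes, although no antibody count had been used to define them. B-like cells were led by IgD, the antigen receptor of mature naive B cells, at 3128 (3115 to 3140), 2931, 3457 (3440 to 3475) and 2783 per 10000 antibody UMI, 10.6 to 22.1 times the mean of the other classes. The complement receptor CD21/CD35 stood at 194, 164, 441 and 248. CD4 stood at 1629, 1556, 1380 and 1489 in CD4 T-like cells, with TCR beta at 140, 132, 162 and 149. CD8b came to 378, 397, 418 and 415 and CD8a to 892, 880, 807 and 663 in CD8 T-like cells, and CD8b to 432, 388, 228 and 460 in the T-like class. Treg-like cells bound the costimulator CD278 (ICOS) at 205, 151, 284 and 328, CD357 (GITR) at 509, 361, 1089 and 372, and the interleukin 2 receptor chain CD25 at 42.5, 51.8, 33.7 and 74.6. CD278 was higher in gamma-delta T-like cells of matrices 1 and 2, at 256 and 288, and in proliferating-like cells of matrices 3 and 4, at 423 and 568, and CD357 was higher in ILC2-like cells of matrices 1 and 2, at 807.5 and 833. NK-like cells were marked by the killer receptors Ly49H, at 511, 429, 951 and 794, and Ly49D, at 185, 175, 257 and 426. ILC2-like cells, with at least 20 cells only in matrices 1 and 2, bound KLRG1 at 303 and 530 and CD25 at 322 and 409. In gamma-delta T-like cells of those matrices the TCR gamma-delta antibody gave 41.8 and 66.6, beside highest isotype controls of 25.2 and 25.3.

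Myeloid and rarer classes were described by antibodies that stood above the mean of the other classes, though not always highest in the class named. Ly-6G, the classical neutrophil antigen, gave 223, 221, 442 and 364 per 10000 in neutrophil-like cells, 25.3 to 60.2 times the mean of the other classes, and the paired receptors PIR-A/B gave 1322, 1452, 1457 and 2175, against 1659, 1730, 1273 and 2027 in classical monocyte-like cells. Classical monocyte-like cells were led by Ly-6C at 323, 176, 187 and 190, and 33.5% of the first value came from 1 cell. In non-classical monocyte-like cells CD274, the inhibitory ligand PD-L1, stood at 222, 224, 510 and 824, but it was higher in migratory DC-like cells of matrices 1 and 2, at 290 and 376. Tim4, a receptor for dying cells, came to 133, 156, 1059 (1017 to 1103) and 1566 (1541 to 1591) in macrophage-like cells, where cluster M8 supplied 33, 48, 0 and 0 cells and cluster M12 supplied 0, 2, 82 and 206. In cDC1-like cells of matrices 1, 2 and 4 it came to 123, 438 and 991, and 1 cell gave 27.6%, 22.2% and 64.6% of these UMI. CD317 marked pDC-like cells at 448, 441, 251 and 470. The basophil-like cells carried the IgE receptor FceRIa at 236, 162, 297 and 275 and CD200R3 at 26.5, 46.0, 44.6 and 74.2. CD138 marked plasma cell-like cells at 2625, 2298 and 1428 in matrices 1 to 3. CD71, the transferrin receptor, reached 1310 and 663 and TER-119 reached 158 and 63.1 in erythroid-like cells of matrices 3 and 4. Platelet-like cells of these matrices bound CD41 at 201 and 269, but also IgD at 1474 and 1676, the antigen that led the B-like class. CD301a stood at 152, 63.1, 259 and 237 in cDC2-like cells and at 89.0, 67.0, 492 and 247 in pDC-like cells. CD117 stood at 820, 572 and 587 in cDC1-like cells of matrices 1, 2 and 4, below the 836 of basophil-like cells in matrix 2, of which 1 cell gave 52.9%, and CD201 led the migratory DC-like cells at 324 and 320 in matrices 1 and 2.

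**Figure D2:**
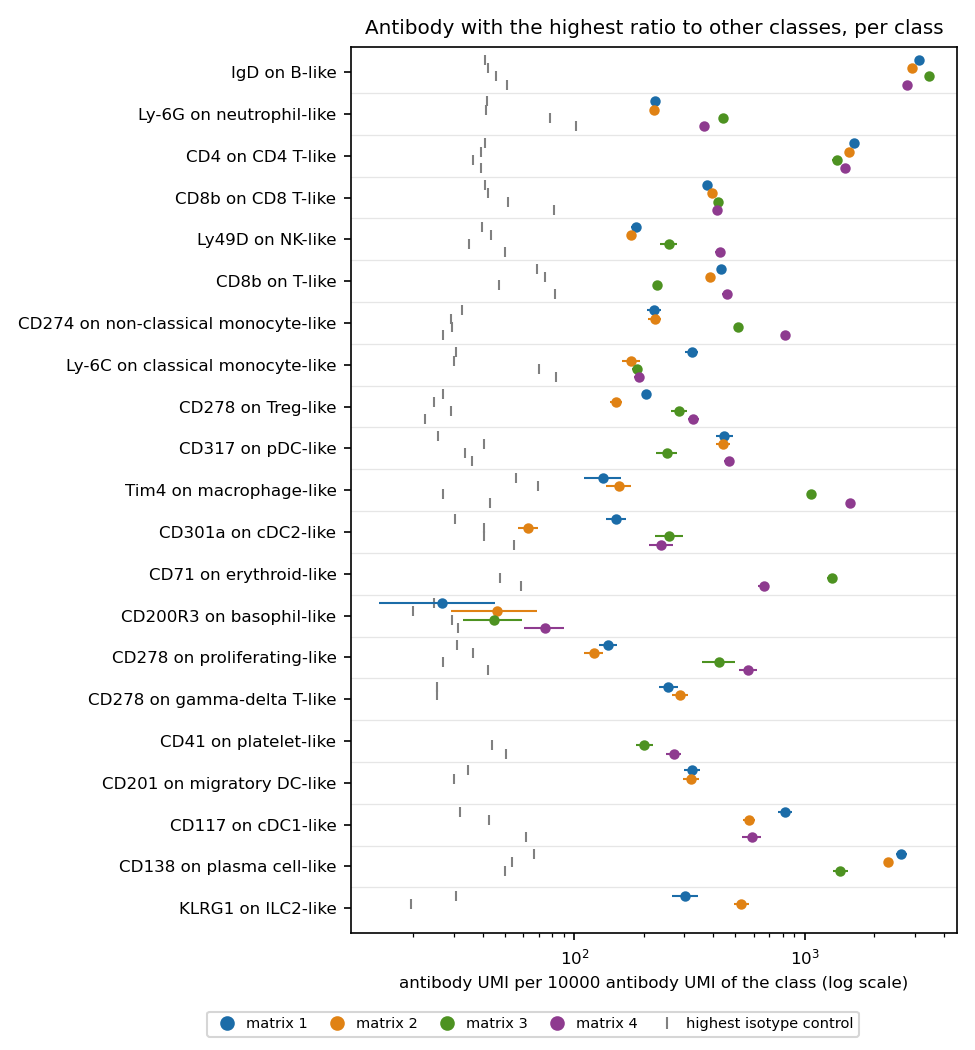
Level of the first-ranked antibody of each RNA-defined class, in UMI per 10000 antibody UMI of the class on a log axis, with 1 point per matrix and a grey tick for the highest isotype control of the same class. IgD in B-like cells lay between 2783 and 3457, while CD200R3 in basophil-like cells, at 26.5 to 74.2, lay closest to its controls.

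Over all classes with at least 20 cells, 615, 598, 503 and 453 pairs of antibody and class exceeded the highest isotype control of that class. With isotype controls that left out the one named IgG2a, which was the highest in every class, the numbers were 1492, 1552, 1137 and 1249, and at 3 times the highest control they were 359, 354, 281 and 254. Among antigens whose antibody epitopes are known to vary between mouse strains, CD90.2 was plainly bound, with its highest values in the T-like class at 1001, 951, 680 and 582. Its allelic counterpart CD90.1 reached no more than 1.17, 0.331, 1.37 and 0.739 in any leukocyte class. CD45.1, the allele that NOD mice are known to carry, peaked at only 0.295, 0.506, 0.124 and 0.164, which a missing allele does not account for, and CD45.2 gave 0 UMI in every matrix. NK1.1, an NK-cell antigen that NOD mice are known to lack, peaked at 6.47, 2.64, 14.9 and 6.78, below the IgG2a control but above the other controls of the same class. The I-A/I-E antibody against MHC class II peaked at 6.98, 2.53, 14.9 and 5.79, again between IgG2a and the other controls, whereas Ly-6C exceeded all controls in 8 of 72 class and matrix pairs.

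CD4 and CD8a antibodies showed that a few RNA-defined T subclusters mixed both lineages. Among cells with at least 5 UMI of the 2 antibodies together, 99.0% of T0 cells in matrix 1 had at least 80% of these UMI from CD4, and 97.1% of T4 cells had at least 80% from CD8a. In T11 the CD4 share was 55.5% and the CD8a share 41.3% in matrix 3, and 48.0% and 50.4% in matrix 4. In T12, a subcluster led by interferon-induced genes, the shares were 39.4% and 53.5% in matrix 1 and 32.0% and 64.9% in matrix 2. T15 had 83.6% and 13.7% in matrix 3 and 80.8% and 19.2% in matrix 4, and T16 had 64.7% and 34.4% in matrix 3. Of the subclusters left unnamed, T6 had 68.2% and 28.8% in matrix 1 and 56.8% and 38.6% in matrix 2, and T10 had 75.2% and 22.0% and 82.7% and 13.5%. The classes named CD8 T-like (T11, T12) and CD4 T-like (T15) therefore contained cells of the other lineage by protein. T11 alone supplied 440 of the 724 CD8 T-like cells of matrix 3.

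**Figure D3:**
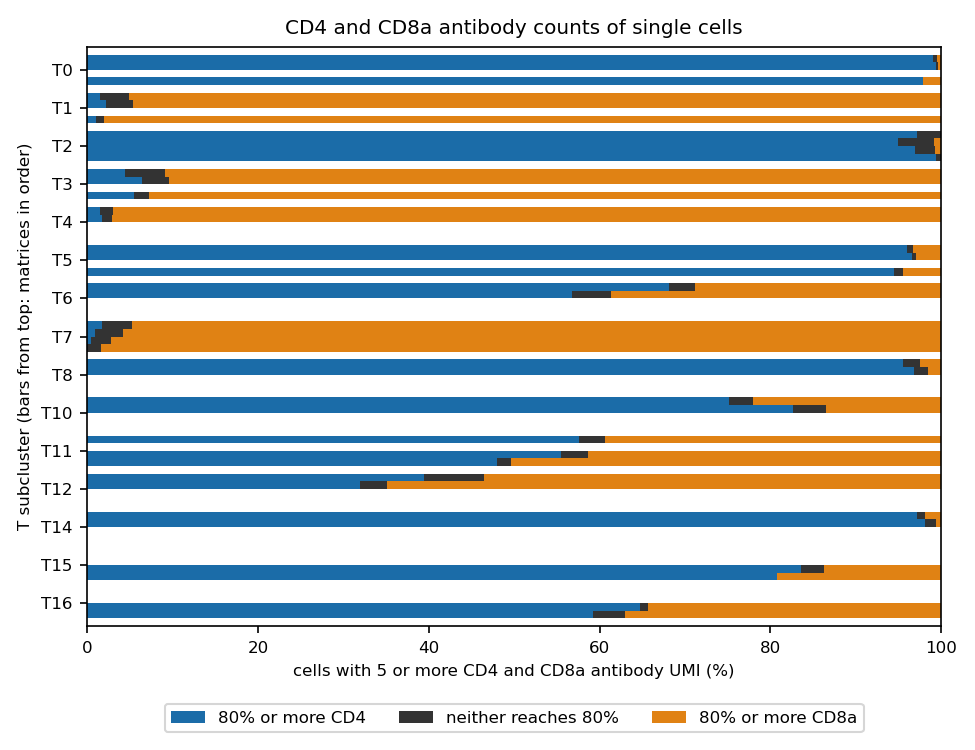
Percent of T cells with at least 5 CD4 and CD8a antibody UMI that had 80% or more of them from CD4, 80% or more from CD8a, or neither, as stacked bars by T subcluster and matrix. T0 was 99.0% CD4 and T4 97.1% CD8a in matrix 1, while T11 was 55.5% CD4 and 41.3% CD8a in matrix 3.

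To ask whether surface protein followed mRNA, each antibody whose target is 1 gene was set against that gene across the classes of a matrix. By the median over matrices, CD4 and Cd4 had the highest Spearman correlation, with 0.966, 0.967, 0.936 and 0.975 in the 4 matrices, although CD5 was higher in matrix 1 (0.979) and CD2 in matrix 4 (0.978). They were followed by CD8a and Cd8a (median over matrices 0.943), CD5 and Cd5 (0.930), CD2 and Cd2 (0.921) and CD11b and Itgam (0.905). The lowest medians belonged to FceRIa and Fcer1a (0.160), Ly-6G and Ly6g (0.170), CD41 and Itga2b (0.198), CD86 and Cd86 (0.318) and CD71 and Tfrc (0.382). Of 19, 19, 17 and 17 classes, FceRIa exceeded the highest isotype control in 1, 1, 2 and 1, Ly-6G in 2, 1, 3 and 2 and CD41 in 1, 1, 5 and 2. Their correlations thus mostly ranked classes in which the antibody was not above this control, which was IgG2a in every class. The number of such classes did not by itself set the correlation. CD314, above the control in 2, 1, 1 and 1 classes, had a median of 0.803, and JAML, in 3, 1, 1 and 1, had 0.822. CD86 had 0.318 although it was above the control in 12, 11, 9 and 8 classes. FceRIa, Ly-6G and CD41 still peaked in the class where their gene peaked in all 4 matrices. These were basophil-like cells for FceRIa and neutrophil-like cells for Ly-6G. For CD41 they were basophil-like cells in matrices 1 and 2 and platelet-like cells in matrices 3 and 4. The median over the 55 pairs was 0.815, 0.761, 0.699 and 0.801, against 0.039, 0.018, 0.000 and -0.020 for mismatched pairs. In 35 pairs the correlation was above 0.5 in every matrix, and in 0 pairs was it below 0 in every matrix. Classes are not independent replicates, so no p-value was computed, and across single cells, most of which had few antibody UMI, the medians were 0.426, 0.438, 0.270 and 0.385.

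The cytotoxic list, summed over its 12 genes, was highest in NK-like cells of matrices 3 and 4 and in basophil-like cells of matrices 1 and 2. NK-like cells had 197.0, 188.0, 313.7 and 322.5 UMI per 10000, CD8 T-like cells 239.9, 202.2, 121.3 and 111.1, and basophil-like cells 357.7, 405.8, 160.3 and 190.9. The basophil-like levels of matrices 1 and 2 rest on 28 and 27 cells. Ccl5, a chemokine gene on chromosome 11 (83525778 to 83530518, GRCm38), reached 162 (161 to 163), 136 (135 to 136), 85.6 (84.3 to 86.9) and 80.1 (79.0 to 81.2) in CD8 T-like cells and 95.2, 99.4, 147 and 156 in NK-like cells. Gzma, a granzyme gene on chromosome 13 (113093825 to 113100981), stood at 32.6 (31.9 to 33.3), 27.2 (26.7 to 27.8), 99.3 (96.8 to 102) and 94.9 (93.1 to 96.8) in NK-like cells. The NK-like class was built from cluster 10, with 4.33%, 6.83%, 0.902% and 0.923% of cells, and cluster 17, with 1.61%, 2.06%, 2.06% and 2.32%, so its Gzma and list levels depended on this mix. Gzma was at 102, 106, 150 and 146 within cluster 17 and at 3.32, 2.13, 11.4 and 6.97 within cluster 10. In basophil-like cells the list's level came from the chemokine genes Ccl4, at 185, 214, 75.4 and 73.7, and Ccl3, at 144, 153, 80.8 and 115. The chemokines list, which shares Ccl5, was highest in CD8 T-like cells of matrices 1 and 2 at 161.8 and 135.8 and in NK-like cells of matrices 3 and 4 at 146.7 and 155.6. Of its other members, Cxcl2 and Ccl2 stood at 6.43, 4.63, 11.2 and 6.11 and at 8.85, 3.48, 0.790 and 0.623 in macrophage-like cells. Cxcl2 was at 7.535, 8.85, 0.661 and 0.847 in neutrophil-like cells and Ccl2 at 7.41, 8.52, 0.164 and 0.397 in classical monocyte-like cells. Cxcl9 was highest in migratory DC-like cells of matrices 1 and 2, at 5.51 and 6.25. Ccl5 and Gzma also served as markers when classes were named, and by protein T11, which dominated the CD8 T-like cells of matrix 3, contained CD4 cells.

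The regulatory list was highest in Treg-like cells in every matrix. It summed to 37.7, 32.9, 28.2 and 31.1 UMI per 10000 there, with Ikzf2, a transcription factor of stable regulatory T cells, at 17.4 (16.8 to 18.0), 14.3 (13.5 to 15.1), 16.2 (14.9 to 17.5) and 16.03 (15.01 to 17.1). Tnfrsf4 and Tnfrsf18, the genes of OX40 and GITR, gave 7.84, 6.84, 2.73 and 3.67 and 6.59, 6.01, 4.01 and 4.78. Il2ra was highest outside the Treg-like cells, in ILC2-like cells of matrices 1 and 2 at 5.18 and 4.16. The inhibitory receptors list also peaked in Treg-like cells, at 14.5, 13.5, 6.66 and 8.79, mostly through 1 gene. This gene, Ctla4, the checkpoint receptor gene on chromosome 1 (60887000 to 60915832), was at 10.8 (10.3 to 11.3), 10.4 (9.71 to 11.1), 4.57 (3.93 to 5.29) and 6.17 (5.54 to 6.85). Entpd1 came to 2.53, 2.83, 2.74 and 3.10 in neutrophil-like cells, and Cd160 to 1.71, 2.36, 0.595 and 0.871 in NK-like cells. Lag3 was highest in cells left unnamed, and in T subcluster T10 it stood at 5.11 and 4.98 in matrices 1 and 2. The helper and follicular list peaked in Treg-like cells at 13.8, 13.2, 7.10 and 9.09 through Icos, at 7.05, 6.51, 5.23 and 6.66, and Izumo1r, at 5.41, 5.23, 1.20 and 1.81. Of its other leading genes, Cd40lg, which helps B cells, stood at 1.67, 1.66, 0.323 and 0.486 in CD4 T-like cells, and Bcl6 at 1.59, 1.53, 1.61 and 2.21 in non-classical monocyte-like cells. Several of the regulatory genes and Ctla4 were among the markers that named the class.

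The naive and stem-like list was highest in CD4 T-like cells of all matrices, at 67.2, 62.3, 68.0 and 71.3 UMI per 10000. The class was made up mainly of T0 and T5 in matrices 1 and 2, whereas T15 supplied 74 of 99 cells in matrix 3 and 580 of 753 in matrix 4. Lef1, a transcription factor of naive T cells, gave 7.69 (7.51 to 7.88), 7.20 (6.99 to 7.41), 8.34 (7.08 to 9.76) and 8.78 (8.32 to 9.25) there, and Il7r, the interleukin 7 receptor gene, 12.9, 11.02, 15.4 and 15.1. Klf2 was at 24.6, 23.0, 14.2 and 14.7 in CD4 T-like cells but higher in neutrophil-like cells, at 44.2, 44.3, 22.9 and 20.1. The tissue residency list stood at 37.5, 42.3, 6.90 and 5.90 in CD8 T-like cells, at 29.6, 29.2, 9.91 and 10.2 in NK-like cells and at 33.5, 47.7, 27.1 and 40.5 in basophil-like cells. In CD8 T-like cells Cxcr6 was at 8.88 (8.66 to 9.10), 10.0 (9.75 to 10.3), 1.47 (1.30 to 1.65) and 0.777 (0.672 to 0.893) and the G-protein regulator gene Rgs1 at 15.5, 18.1, 1.61 and 1.41. Different subclusters made up the CD8 T-like class, T3 and T4 in matrices 1 and 2, T11 and T7 in matrix 3 and T7 in matrix 4. In basophil-like cells the early activation gene Cd69 gave 19.5, 30.6, 4.64 and 5.38 and Rgs2 gave 6.29, 10.7, 13.6 and 25.5.

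Inflammatory genes reached a high level in neutrophil-like cells, where Il1b had its highest value of any class and matrix. The inflammatory list summed to 217.7, 227.3, 89.5 and 129.4 UMI per 10000 in these cells, nearly all of it Il1b, the interleukin 1 beta gene on chromosome 2 (129364570 to 129371139), at 197.0 (194.5 to 199.5), 206.8 (204.0 to 209.6), 81.8 (80.8 to 82.8) and 120.0 (119.2 to 120.9). Of cells drawn down to 500 UMI each, 98.7%, 99.3%, 93.0% and 96.7% of neutrophil-like cells had an Il1b UMI (99.4%, 99.5%, 97.7% and 99.4% at full depth). The same shares in B-like cells, which should lack it, were 0.472%, 0.691%, 8.22% and 1.88% (3.19%, 4.18%, 19.0% and 10.8% at full depth), and the median depths in matrix 1 were 2171 and 3325 UMI. Ptgs2 stood at 13.7, 13.75, 2.90 and 4.29 and Nlrp3, the inflammasome sensor gene, at 4.48, 4.42, 2.95 and 3.06 in neutrophil-like cells. In basophil-like cells Ptgs2 was at 14.9, 11.7, 2.78 and 1.86, and Il6 was highest there, at 13.3, 14.0, 4.25 and 2.22. The dissociation stress list, genes that respond to handling of tissue, was highest in neutrophil-like cells, at 242.2, 245.5, 95.5 and 116.8. There Junb stood at 86.6, 87.7, 44.0 and 55.6, Fos at 67.4, 66.9, 17.2 and 24.0 and Dusp1 at 53.5, 54.0, 30.7 and 33.5. In basophil-like cells this list came to 199.1, 208.0, 58.7 and 108.0, with Jun at 43.8, 55.2, 3.44 and 6.79. Neutrophil-like cells came from cluster 3 in 490, 400, 869 and 2999 cells and from cluster 9 in 27, 19, 1913 and 265.

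Genes of antigen presentation separated the macrophage-like cells of matrices 1 and 2, mainly cluster M8, from those of matrices 3 and 4, cluster M12. The list, with 9 of its 10 genes measured, summed to 676.6, 616.8, 5.18 and 6.72 UMI per 10000 in macrophage-like cells, to 534.6, 596.1 and 544.6 in cDC1-like cells of matrices 1, 2 and 4, and to 536.0, 531.3, 309.2 and 410.8 in cDC2-like cells. Cd74, the invariant chain that guides MHC class II assembly, was at 286.2 (279.4 to 293.2), 278.0 (272.1 to 284.0), 1.099 (0.846 to 1.40) and 2.05 (1.88 to 2.23) in macrophage-like cells, against 181.1, 194.0, 149.2 and 197.6 in B-like cells. The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 went the same way, with H2-Aa at 147, 129, 0.584 and 0.692, H2-Ab1 at 116, 98.2, 0.515 and 0.406 and H2-Eb1 at 108, 92.6, 0.172 and 0.321. In matrix 3 macrophage-like cells made up 1.04% of hashtag 1 cells, 0% of hashtag 2 cells and 1.09% of cells given to neither. Cluster M8 supplied 33 and 48 of the macrophage-like cells in matrices 1 and 2. Cluster M12 supplied 82 and 206 in matrices 3 and 4, so the values belong to different clusters. The same holds for cDC2-like cells, of which clusters M3 and M6 supplied 76 of 93 and 102 of 114 in matrices 1 and 2, and M5 and M11 supplied 88 of 89 and 56 of 58 in matrices 3 and 4. Of these, M6 also met 6 macrophage markers, against 5 cDC2 markers, with Retnla and Mrc1 among its leading genes. The interferon response list was highest in pDC-like cells of all 4 matrices, at 54.5, 51.9, 60.5 and 63.1, through Bst2, the gene of CD317 and itself a pDC marker, at 50.4, 47.7, 57.2 and 59.1. Of its other leading genes, Rsad2 stood at 4.56 and 4.85 in erythroid-like cells of matrices 3 and 4 and Isg15 at 0.0691, 5.03, 0.111 and 0.332 in basophil-like cells.

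Proliferating cells were few, at 1.34%, 1.12%, 0.278% and 0.330% of cells. The proliferation list summed to 63.8, 61.8, 44.7 and 56.3 UMI per 10000 in them, with Tubb5 at 18.4, 18.2, 11.3 and 14.8, Stmn1 at 9.91, 8.94, 8.76 and 8.95, Top2a at 9.60, 8.67, 5.69 and 7.07 and Mki67 at 7.90, 9.04, 4.83 and 7.91. Top2a and Mki67 also named the class. The germinal centre B list peaked in the same class at 10.3, 12.5, 5.55 and 8.37, but Mki67 is 1 of its 5 members and made up most of these sums, so the peak follows from how the class was named. Cluster M0, led by Rgs13 and Mef2b, supplied 40, 50, 1 and 2 of the proliferating cells, and in it Fas stood at 1.55 and 1.30 in matrices 1 and 2. Fas and Bcl6 of this list were otherwise highest in neutrophil-like and non-classical monocyte-like cells, Fas at 1.64, 1.60, 1.61 and 1.86 in the former.

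Genes of other cell types the sort or the tissue could have brought along were counted in the same way. The erythroid list summed to 7960 and 5883 UMI per 10000 in erythroid-like cells of matrices 3 and 4, with Hbb-bs at 3821 (3807 to 3834) and 2893 (2879 to 2907), Hba-a1 at 3030 and 2111, Hbb-bt at 1009 and 802 and Hba-a2 at 85.3 and 59.9. Hba-a1 and Hba-a2 are near-identical copies, so their split is uncertain. In B-like cells, which should lack it, Hbb-bs was at 0.0372, 0.0248, 3.19 and 1.35. The platelet list reached 28.3 and 28.6 in platelet-like cells, with Ppbp at 12.1 and 12.3, Pf4 at 10.6 and 10.4, Itga2b at 3.58 and 2.74 and Gp9 at 1.96 and 3.14. The pancreas parenchyma list came to 4.63, 1.32, 0.0225 and 0.0459 in neutrophil-like cells and to 2.25, 7.22, 0.0172 and 0.0155 in macrophage-like cells. Ctrb1, the chymotrypsinogen gene on chromosome 8 (111686519 to 111691010), stood at 0.668 (0.624 to 0.715) and 0.386 (0.352 to 0.423) in B-like cells of matrices 1 and 2, while 0 UMI were counted there in matrices 3 and 4, which allows up to 0.00752 and 0.00368. Most Ctrb1 UMI of B-like cells in matrices 1 and 2 lay in cluster 13, at 1.88 and 2.29, against 0.186 and 0.0515 in cluster 1. Cluster 13 met 7 acinar markers besides its B markers. A small cluster of 136, 40, 0 and 0 cells was led by acinar genes, with Ctrb1 at 143 and 155, Prss2 at 47.0 and 51.2, Pnlip at 38.8 and 36.2 and Cela3b at 34.4 and 36.6 in matrices 1 and 2. Of its acinar UMI, 81.9% and 54.6% lay in 4 and 2 cells, its median cells had 0.187% and 0.207% of their UMI from 8 acinar genes, and the cluster also met 5 markers of the CD4 T list.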

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

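Hashtags outside the 2 that marked cells, and the streptavidin features of the antibody panel, entered no comparison. The values here were picked out because they exceeded a set floor of 3 UMI. All counts are totals over a matrix, and no test of their origin was run, so no biological explanation was tested. Hashtag3 gave 55, 40, 14 and 14 UMI in matrices 1 to 4, against 211380, 155026, 43873 and 62384 UMI of Hashtag1. Hashtag14 gave 6 UMI in matrix 1 and 13 in matrix 2. Of the biotin hashtags, Hashtag3_biotin gave 4 UMI in matrix 1, and in matrix 3 Hashtag1_biotin gave 4, Hashtag4_biotin 4, Hashtag5_biotin 7 and Hashtag9_biotin 7. A streptavidin feature gave 6 UMI in matrix 1 and 4 in matrix 2.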

How the results depend on the processing

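Keeping doublets moved 16 of 84 class shares, 41 of 335 ratios of leading antibodies, 19 of 241 named gene levels and 5 of 64 list levels by more than 1.5 times. It gave B-like shares of 28.4%, 29.0%, 24.5% and 27.0% in matrices 1 to 4 and neutrophil-like shares of 4.97%, 28.2% and 32.9% in matrices 2 to 4, and turned CD5 and CD4 in proliferating-like cells of matrix 3 from above to below the mean of other classes, at 0.853 and 0.706 times. Class shares moved this far in 10 of 84 with a limit of 5% mitochondrial UMI, 7 with a minimum of 500 genes, 11 and 6 at resolutions 0.5 and 2.0 and 4 with receptor genes kept. The mitochondrial limit gave 22.1% B-like cells in matrix 3 and 32.5% and 33.2% neutrophil-like cells in matrices 3 and 4, where a minimum of 500 genes gave 22.3% and resolution 2.0 gave 25.8% neutrophil-like cells in matrix 3. At 3 times the highest isotype control, 359, 354, 281 and 254 pairs of antibody and class remained. Over single cells the median rho of RNA and protein was 0.426, 0.438, 0.270 and 0.385, and rho of Ly-6G and Ly6g in matrix 3 turned positive at 0.210, while the centred log-ratio gave a median of 0.725 in matrix 3. After thinning, 31 of 244 named gene levels and 1 of 64 list levels moved this far. Gene lists kept their highest class in 15, 14, 16 and 15 of 16 after thinning and in 15, 14, 15 and 15 with doublets kept. Another 3 settings were chosen after seeing the data. Only cells with 1 hashtag moved 17 of 84 shares this far and gave neutrophil-like shares of 3.91%, 11.1% and 22.8% in matrices 1, 3 and 4 and B-like shares of 29.8% and 33.1% in matrices 3 and 4. Isotype controls without IgG2a gave 1492, 1552, 1137 and 1249 pairs, by construction, because the highest control was left out. Without the cell with the most UMI, 22 of 360 ratios of leading antibodies moved this far and CD150 in proliferating-like cells of matrix 3 fell to 0.891 times other classes. The cause of the other changes was not tested. No paired analysis was possible because no matrix or hashtag could be tied to a mouse. The planned tissue tests were not run for the same reason, and neither were their alternatives: another count test or normalisation, no low-count filter, a replicate block, leaving out 1 sample, a pseudocount of 0.1 and sign flips.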

Other observations

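In this part, the tests of free acinar RNA by its spread over cells and of CD4 and CD8a antibodies on single cells were set before their results were seen, and the other tests were chosen after.

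A small T subcluster, T10, combined helper and inhibitory genes and stayed unnamed, because its 10 leading genes held the Treg marker Tnfrsf4 but no CD4 T marker. It had 141, 105, 0 and 1 cells in matrices 1 to 4 and was led by Il21, a cytokine gene of B-cell help, by the checkpoint receptor gene Lag3 and by the anti-inflammatory cytokine gene Il10. In matrices 1 and 2 its levels were 3.22 and 2.95 UMI per 10000 for Il21, 5.11 and 4.98 for Lag3, 1.90 and 2.07 for Il10, 8.12 and 8.22 for Ctla4 and 1.97 and 1.90 for Pdcd1. Cxcr5, the receptor that takes follicular helper cells into B-cell follicles, was low at 0.340 (0.220 to 0.501) and 0.0766 (0.0209 to 0.196), as was the regulatory gene Foxp3 at 0.136 and 0.0575. By protein T10 bound CD4 at 1186 and 1420, CD73 at 373 and 454 and CD278 at 178.1 and 186 per 10000 antibody UMI, each above its highest isotype control of 30.3 and 26.9, while CD279, the protein of Pdcd1, was below it at 8.59 and 10.1. Of its cells with at least 5 CD4 and CD8a UMI, 75.2% and 82.7% were CD4 cells by antibody and 22.0% and 13.5% CD8 cells, with Cd8a RNA at 10.8 and 11.5 in the latter, so T10 held both lineages. CD304 stood at 420 in matrix 1, but 99.0% of it came from 1 cell. Its genes were chosen after their values were seen.

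Interferon-induced genes also defined small groups within larger classes. Subcluster T12, with 110, 109, 3 and 3 cells, had Isg15 at 13.6 and 13.8 and Ifit1 at 11.1 and 11.2 UMI per 10000 in matrices 1 and 2, and B-like cluster 21, with 58, 33, 2 and 24 cells, had Ifit3 at 7.78, 8.75 and 7.03 in matrices 1, 2 and 4. Another B-like cluster, 19, with 77, 144, 57 and 152 cells, was led by Zbtb32 and Bhlhe41 and stood apart in antibodies, with CD5 at 171.4, 144, 140 and 189 and CD43 at 249, 141, 392 and 168 per 10000, and IgD at 1161, 889.5, 928 and 881 beside 3128, 2931, 3457 and 2783 in B-like cells as a whole. The 2 NK-like clusters differed in the same readouts, since cluster 17 bound Ly49D at 717, 744, 393 and 668 against 9.79, 20.6, 13.8 and 21.9 in cluster 10, and Gzma was at 102, 106, 150 and 146 there against 3.32, 2.13, 11.4 and 6.97 in cluster 10. Proliferating cluster M0, led by Rgs13 and Mef2b, bound CD95, the protein of Fas, at 80.6 and 56.1 in matrices 1 and 2.

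Several values fell into separate ranges over the 4 matrices. Neutrophil-like shares were 4.61%, 4.51%, 26.7% and 31.7%, gamma-delta T-like shares 1.25%, 1.67%, 0.0192% and 0.0486%, and platelet-like shares 0% (up to 0.0329%), 0% (up to 0.0397%), 1.84% and 0.825%. UMI of the 8 acinar marker genes outside the acinar-led cluster came to 1.99, 1.15, 0.0277 and 0.0209 per 10000. No matrix was assigned to a tissue on these grounds.

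Acinar enzyme transcripts were found in leukocyte classes although cells had been sorted for CD45, and acinar cells are a candidate source, as a hypothesis, from the marker list Prss2, Cela1, Cela2a, Cela3b, Ctrb1, Cpa1, Cpb1 and Pnlip, all 8 of which also stand in the pancreas parenchyma list. Whole acinar cells caught with a leukocyte are argued against as the bulk of the acinar-led cluster, since its median cell had at most 0.207% of its UMI from the 8 genes. However, 4 cells of matrix 1 and 2 cells of matrix 2, with 20% or more of their UMI from these genes, held 81.9% and 54.6% of the cluster's acinar UMI. A median of 8 of the 8 genes was seen in them. This cannot decide whether they were whole acinar cells, alone or with a leukocyte, because they were picked by the same genes and had median depths of 10219.5 and 4641.5 UMI. The leukocyte gene Ptprc was counted in 4 and 1 of them. In the cluster Ctrb1 averaged 143 and 155 and Prss2 47.0 and 51.2 UMI per 10000 in matrices 1 and 2. Free RNA cannot be told apart from other routes by its spread, because the 1% of other cells with the most acinar UMI held 2.28 times the Poisson expectation in matrix 1 and 3.53 times in matrix 2, between the limits of 2 and 5 set beforehand, and the higher Ctrb1 of B-like cluster 13 than of cluster 1 (1.88 and 2.29 against 0.186 and 0.0515) decides nothing, as clusters were made from RNA and it was not tested whether acinar RNA drew these cells together. In favour of 1 shared profile, the interval of the Ctrb1 part of the 8 genes included that of the other classes in 94.4% of leukocyte classes and matrices (34 of 36). It included that of the acinar-led cluster, which rests on few cells, in 55.6% (20 of 36). Both tallies depend on the width of the intervals. In B-like cells of matrix 1, with 2741 such UMI, it ran from 29.03 to 32.52%, against 40.96% in the cluster. In pDC-like cells of matrix 2, with 26 such UMI, it ran from 29.93 to 70.07%, against 41.25%. B-, CD4 T-, CD8 T- and NK-like cells lay outside in both matrices. Thus 1 source within a matrix cannot be told apart from several, and no biological explanation was tested.

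Antibodies against CD45, CD49b and CD371 stayed below 1 UMI per 10000 in every class although their genes were expressed, and CD45.2 had 0 UMI in all 4 matrices while its gene Ptprc reached at least 27.3 UMI per 10000 in some class of each. Low antibody depth is argued against for CD45 and CD45.2, since in the class with the most Ptprc RNA their upper 95% limits were at most 0.217 times the highest isotype control other than IgG2a, but it cannot be told apart from other causes for CD49b and CD371, where this ratio reached 3.69 and stayed below 1 in 4 of 8 antibody and matrix pairs. For a strain epitope as the whole cause, 3 of these antibodies (CD45, CD49b and CD371) were not among the antigens taken here to vary between strains. This cannot decide the question, because that set came from general knowledge and the limit of 3 antibodies was set after the values were seen. Low depth also stays open for CD49b and CD371. A strain epitope stays open for CD45.2. Competition with the sort antibody, which also bound CD45, and reagents missing from the pool stay open as well. Ly6D and 1 of 2 CD278 antibodies likewise gave 0 UMI in all 4 matrices while the other CD278 antibody gave 7593 in matrix 1. Antibodies named CD3e, at 2, 0, 3 and 3 UMI, and Ly6G/Ly6C, at 0, 0, 2 and 0, were also near 0 but were not part of these tests. The antibodies named CD3 and Ly-6G gave 9114 and 2710 in matrix 1. No biological explanation was tested.

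CD4 and CD8a antibodies both bound to T subclusters T11, T12, T15 and T16, and a candidate explanation is that CD4 and CD8 cells with similar RNA were placed in 1 cluster. Single cells fit this, as in each of the 4 subclusters, over all matrices, at least 95.02% of cells with 5 or more UMI of the 2 antibodies had 80% or more of them from 1 antibody. Doublets of a CD4 and a CD8 cell are argued against, because cells with both antibodies were 0.0466 times as frequent there as among T-cell hashtag doublets (1.63% of 2275 cells against 34.9% of 341). T6 and T10 were mixed too but were not part of these tests, and no biological explanation was tested.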
